A study of Mus musculus with 20 samples.

How the data were processed

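The samples were livers of male C57BL/6J mice, an inbred laboratory strain, fed for 4 weeks either a low-fat diet (10% of energy from fat) or a high-fat diet (45% of energy from fat). Animals were killed after a fast of 16 h. Per the labels' protocols, total RNA was turned into biotin-labelled RNA with a 3′-end kit and hybridised to Affymetrix arrays, 1 array per mouse and 10 mice per diet. The design text also describes high-fat groups given a maple syrup extract, which are not analysed here.

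The deposited values are a probe set score, 1 column per array, and the method that summarised and normalised the probes is not given in the sources used here. The level of these scores runs like a log2 intensity, from 5.18 to 15.00 over the 45037 probe sets that are not controls. Their differences between arrays are far smaller than log2 intensities of single animals give: the median SD over the 20 arrays was 1.17e-05, and 44238 probe sets (98.2%) had an SD below 0.001, while the largest SD was 0.349. The compression thus differed between probe sets. A difference between diets in the deposited score is therefore not a log2 fold change, and its size cannot be compared between genes. The design fixed before the data were examined had assumed log2 values. The planned test was kept because a linear model for each gene does not depend on a gene's own scale, but sizes are given here as standardised differences: the mean of the high-fat mice minus that of the low-fat mice, divided by the pooled SD within diets, with a 95% interval from the noncentral t distribution. The share of the 100 pairs of a high-fat and a low-fat mouse in which the high-fat mouse was higher is given as a measure that needs only the order of the values. Both rest on the score of a probe set rising with its transcript, which was not tested.

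Gene names came from the platform annotation of the probe sets. Of the probe sets, 34945 had 1 gene symbol, 932 had several and were given no name, and 9160 are unnamed here; 64 controls were left out of the gene and list tests and tested apart. Of those with 1 symbol, 34741 matched the gene table of assembly GRCm38.p6 by gene identifier, and 0 symbols changed. Each of the 18193 genes was represented by its named probe set with the highest mean over the 20 arrays. No filter on low values was used. The file held 0 columns of other samples.

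Diets were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The prior had 0.724 degrees of freedom, so variances were shared only weakly between genes. It still lowered the statistic of genes with very small SDs. Gene lists, 30 of pathways and 12 of cell types, were fixed before the data were examined and tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over all 42 lists. Of their 690 entries, 84 had no named probe set here and were not tested. After the data had been seen, each list's mean standardised value per mouse was also compared by a two-sided permutation test of the mice with 100000 resamples, because the preset correlation ignores how strongly members of a list vary together. Values were divided by each gene's SD within the real diets, which was not recomputed for permuted mice. That can favour the real split, by an amount that was not examined.

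Named genes followed a rule fixed before the data were examined: the 10 largest rises and the 10 largest falls in the deposited score among genes past the threshold, leaving out predicted or unnamed gene models, the 3 members with the smallest adjusted p of each list past its threshold, and at most 1 such member of each other list. Because of the compression, the first part of the rule favours probe sets whose scores were compressed least. Genes named outside the rule are said to be so.

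Alternatives planned beforehand were quantile normalisation, centring of arrays on their median, the upper part of features by mean, a variance trend with robust fitting, array weights, the replicate number as a block, probe sets with cross-hybridising suffixes left out, the mean of a gene's probe sets, an exact Wilcoxon rank sum test (midranks for ties), a threshold of 0.01, an estimated inter-gene correlation, fry, and leaving out each array. Added after seeing the data were an unmoderated model, array centring on standardised values, a control probe set for the B2 repeat as a covariate, the mean standardised score of 24 poly-A spike-in control probe sets as a covariate, and the permutation of the mice.

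The gene fit was tested on simulated data with the 18193 genes' own means and SDs and 200 changed genes. Of genes shifted by 1 SD, 4% were recovered, of those shifted by 2 SD, 56%, and of those shifted by 3 SD, 96%, with 4 false calls. For lists, 1 shifted list of 42 was recovered and 0 other lists were called. The simulated genes varied independently of each other. Members of real lists vary together, with an estimated correlation of 0.570 for the chaperones and 0.374 for cholesterol synthesis. The simulation therefore does not measure false list calls in these data. The number of arrays limits the precision. The values give no scanner signal, so signal over background was not examined.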

Results

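Liver transcript scores were compared between 10 mice on a low-fat diet and 10 on a high-fat diet, each mouse measured on its own array. The comparison asks what 4 weeks of high-fat feeding changed in the fasted liver. Array medians ran from 6.56702 to 6.5672 and were higher in the high-fat mice by 7.33e-05 (95% interval 2.16e-05 to 0.000125, permutation p = 0.0102), or 1.33 SD, and 0 pairs of arrays held identical values. Sizes are standardised differences in units of the SD within diets, since the deposited scores are compressed. Acaca, Fasn, Acly, Elovl6, Cpt1a, Herpud1, Xbp1, Hmgcs1, Cyp7a1, Cyp3a13, Cyp3a16, Cyp3a44, Sod2, Gstt1, Abcc2, Sult1e1, Ndufa6, Sdhd, Apcs and Slc10a1 lie outside the rule for named genes and were chosen after their values were seen.

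On the high-fat diet, genes of the endoplasmic reticulum folding machinery and of cholesterol synthesis were higher, and the fatty acid desaturase gene Scd1, the apolipoprotein gene Apoc2 and the drug-metabolising cytochrome gene Cyp3a11 were lower. Of the cholesterol synthesis genes 7 of 17 passed, and that list lost its call with an estimated correlation (adjusted p = 0.123). Scd1, which makes monounsaturated fatty acids, fell from 12.875 ± 0.00112 to 12.859 ± 0.00349 in the deposited score (mean ± SD, n = 10 per diet), a standardised difference of -6.33 (95% interval -8.54 to -4.09). All 10 high-fat mice lay below all 10 low-fat mice for Scd1, Apoc2 and Cyp3a11. By limma, 635 of 18193 genes passed an adjusted p of 0.05, 312 of them higher and 323 lower on the high-fat diet. Over all probe sets, 1043 of 45037 passed, 501 higher and 542 lower. Of 378 genes past the threshold with several probe sets, 255 had all of these in the same direction. Values of a gene are those of its representative probe set, and its other probe sets are given only for some genes. The diets were completely separated by 50 of all genes tested, against 0.197 expected by chance, and 49 of these genes passed the threshold. The balance of directions depended on scaling: 144 genes were higher and 1344 lower after quantile normalisation (868 genes left with 1 value on all arrays gave no test), and 215 higher and 14883 lower after centring arrays on their medians. Those scalings shifted the median standardised difference of all genes from 0.04 to -0.41 and -1.29. Median centring takes the difference in array medians (7.33e-05) from every gene. The probe sets do not share it: 5 probe sets made up the 20 medians, the median difference of a probe set was 2.63e-07, and 52.2% were higher on the high-fat diet.

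**Figure D1:**
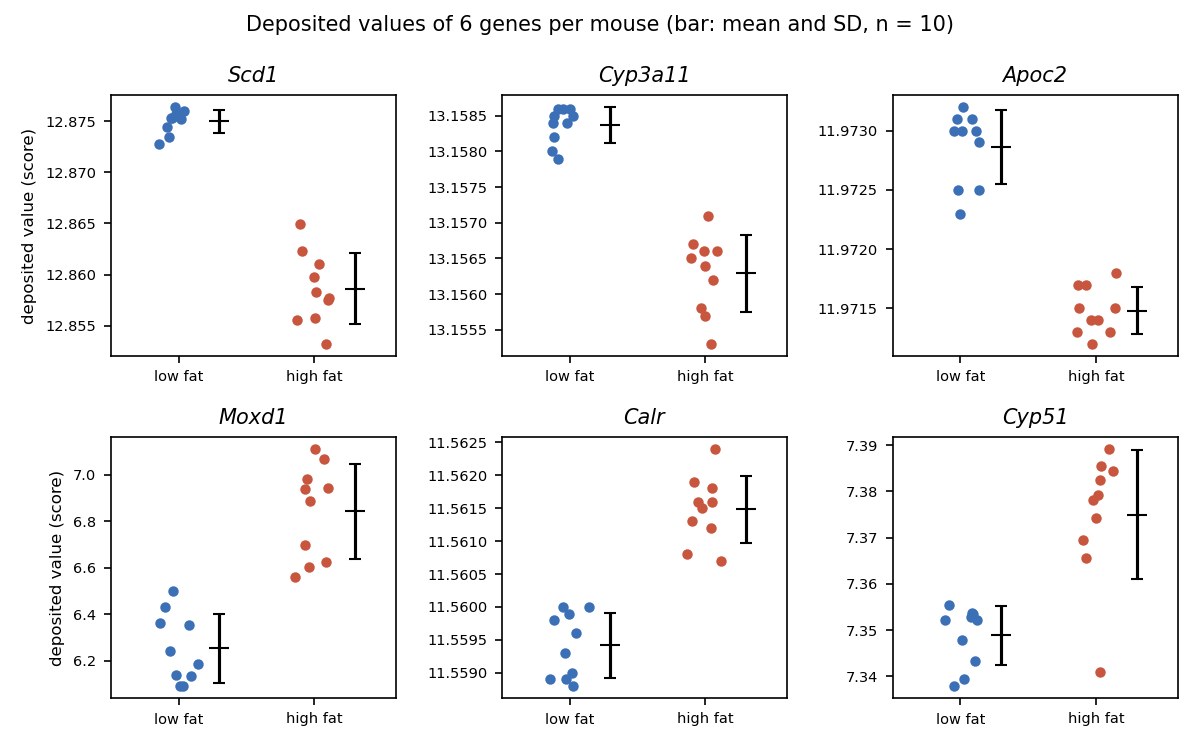
Deposited scores (vertical axes, no unit) of 6 genes in each of the 10 low-fat and 10 high-fat mice, with the mean and SD as bars. Scd1, Cyp3a11 and Apoc2 are lower and Moxd1 and Calr higher in all high-fat mice, while 1 high-fat mouse lies among the low-fat mice for Cyp51.

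In fatty acid synthesis and desaturation, 4 of 17 measured members fell and 0 rose (5 fell when adjusted over the list alone; camera adjusted p = 1.35e-05, and adjusted p = 0.00639 with an estimated correlation). After centring arrays on their medians, which lowers most genes, that list had an adjusted p of 0.613. Besides Scd1 the members that fell were Fads1, a desaturase of polyunsaturated fatty acids (-3.42, 95% interval -4.82 to -1.99), Me1, a cytosolic source of NADPH (-2.40, -3.55 to -1.21), and Acaca, which makes malonyl-CoA (-2.07, -3.15 to -0.95). Other probe sets of Fads1 (0.94, adjusted p = 0.316), Me1 (-1.28, adjusted p = 0.144) and Acaca (-0.17, adjusted p = 0.906) did not pass. The fatty acid synthase gene Fasn (-0.32, 95% interval -1.20 to 0.57), Acly (-0.51, -1.39 to 0.39) and Elovl6 (-0.74, -1.64 to 0.18) did not pass. Khk, which phosphorylates fructose, was the only 1 of 8 measured genes of glycolysis and sugar handling to fall (-2.36, adjusted p = 0.00481); 1 also fell when adjusted over the list alone. That list did not pass by camera (adjusted p = 0.0847) and passed the permutation of mice (score difference -0.58 SD, adjusted p = 0.0439). It did pass by camera without cross-hybridising probe sets (0.0483) and with the mean of a gene's probe sets (0.0481).

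Among genes of lipoproteins and HDL, 3 of 14 fell and 0 rose, the same numbers when adjusted over the list alone. They were Apoc2, a cofactor of lipoprotein lipase (-5.18, 95% interval -7.05 to -3.27), Pltp, which transfers phospholipids between lipoproteins (-2.46, -3.63 to -1.26), and Apoa4 (-1.86, -2.90 to -0.78). Another probe set of Pltp did not pass (-1.23, adjusted p = 0.161). The list's camera adjusted p was 0.0447, with adjusted p = 0.0778 with an estimated correlation. That call ended in 9 of 14 other settings, among them the replicate block (0.144), the upper features by mean (0.0824), the variance trend (0.0814) and the omission of cross-hybridising probe sets (0.0515), and in 9 of 20 fits without 1 array (up to 0.0785, without high-fat replicate 2). Lipid droplet genes and PPAR-gamma targets had the same adjusted p-values (0.0447 by camera and 0.0778 with an estimated correlation), and the call was lost in 6 of 14 other settings and 8 of 20 such fits (up to 0.137, without high-fat replicate 3). In the permutation of mice both lists passed (adjusted p = 0.0171 and 0.0231). That test takes the mean of a list and does not compare it with other genes, so a few far members can carry it. The lipoprotein list had a mean of -0.62 and a median of -0.28, and 4 of its 14 members were higher. Of the lipid droplet list 0 of 16 members passed, 2 fell when adjusted over the list alone, and 14 were below the low-fat mean. In mitochondrial fatty acid oxidation only Etfb, a subunit of an electron carrier, passed (1.68, adjusted p = 0.0439, of 16 measured), a call lost in 14 of the 20 fits that left out 1 array (adjusted p up to 0.0779, without low-fat replicate 8), with the rank sum test (0.0575) and with array weights (0.0881). After median centring Etfb stood at -1.12 (limma adjusted p = 0.0274), a call in the other direction. Adjusted over the list alone, 2 members of that oxidation list rose and 1 fell. Cpt1a stood at 0.19 (95% interval -0.69 to 1.07). Of the peroxisomal and omega oxidation list 0 of 16 passed, and of ketone body synthesis 0 of 3.

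In the list of endoplasmic reticulum chaperones 14 of 15 measured members rose, over all genes and adjusted over the list alone (camera adjusted p = 6.98e-23, and adjusted p = 0.0258 with an estimated correlation). Calr, a calcium-binding lectin chaperone, stood at 4.15 (95% interval 2.53 to 5.74), Pdia6, a protein disulfide isomerase, at 3.19 (1.81 to 4.52), and Hspa5, the BiP chaperone, at 2.99 (1.66 to 4.27). Sdf2l1 (2.74) and Creld2 (2.24), also of the secretory pathway, were among the 10 largest rises. Herpud1 was the member that did not pass (0.90, adjusted p = 0.310). Like Herpud1, the member Xbp1 (2.49, adjusted p = 0.00339) encodes no chaperone. All 15 members were higher under both kinds of array centring tried, and 13 of the 14 that had differing values after quantile normalisation, which left Calr with 1 value on all arrays. In the permutation of mice the mean score of the list was higher by 2.47 SD (adjusted p = 0.00028), and all 10 high-fat mice lay above the low-fat median.

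The proteasome list was higher (camera adjusted p = 3.87e-08; adjusted p = 0.02 with an estimated correlation, and 0.186 after quantile normalisation), but only Psma4 of 29 members rose, and 5 when adjusted over the list alone. Of the proteasome members 10 of 23 were higher after quantile normalisation and 3 of 29 after median centring. Of 11 heat shock genes only Hspd1, a mitochondrial chaperonin, rose, also adjusted over the list alone (camera adjusted p = 0.00192; adjusted p = 0.354 with an estimated correlation). Neither list passed the permutation of mice (adjusted p = 0.0856 and 0.0955). The signs of Psma4 (-0.766) and Hspd1 (-0.949) turned after median centring. Asns, which makes asparagine and responds to amino acid shortage, rose (2.13, adjusted p = 0.00964) from a low-fat mean of 6.43, below the array median of 6.57. Its ATF4 list missed the camera threshold (adjusted p = 0.0847) and passed the permutation of mice (score difference 0.48 SD, adjusted p = 0.00028). The list also passed by fry (0.00296) and by camera with the mean of a gene's probe sets (0.0180). It passed after median centring too (1.53e-10), but that setting lowers most genes, and 21 of 42 lists passed there.

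**Figure D2:**
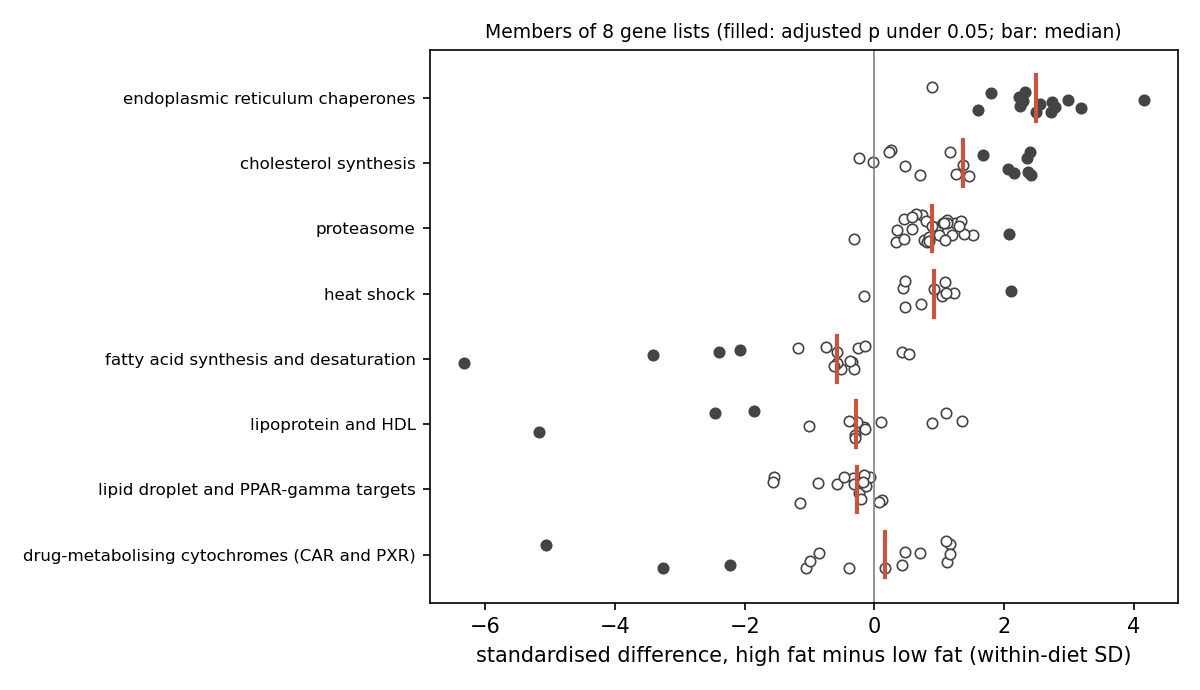
Standardised differences (horizontal axis, SD within diets, high fat minus low fat) of the measured members of 8 lists, each point a gene, filled where the adjusted p was under 0.05, with the list median as a bar. The 15 members of the chaperone list all lie above 0, while the fatty acid list holds a few far members, with Scd1 at -6.33, and a median of -0.58.

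Cholesterol synthesis genes rose in 7 of 17 members and fell in 0, and in 11 when adjusted over the list alone (camera adjusted p = 9.66e-09; adjusted p = 0.123 with an estimated correlation, so that call was lost). The permutation of mice gave a score difference of 1.30 SD (adjusted p = 0.00651). Msmo1 (2.42, 95% interval 1.22 to 3.58), Cyp51 (2.40, 1.21 to 3.55) and Idi1 (2.37, 1.19 to 3.52) are all enzymes of the pathway, and Sqle, which epoxidises squalene, stood at 2.06 (0.94 to 3.14). Another probe set of Msmo1 did not pass (0.07, adjusted p = 0.962). Hmgcs1, an early enzyme, stood at -0.23 (95% interval -1.11 to 0.65). Cyp7b1, an oxysterol hydroxylase of bile acid synthesis, rose (2.56, adjusted p = 0.0028), whereas Cyp7a1, the rate-limiting enzyme of the classical route, stood at 0.63 (-0.27 to 1.53). The transporter gene Slc10a1 fell (-1.64, adjusted p = 0.0440). These were the only 2 of the 17 members of the bile acid list to pass, 2 rose and 2 fell when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.892).

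The list of drug-metabolising cytochromes had 15 measured members, among them the genes Gstt1, Abcc2 and Sult1e1, which encode no cytochromes. Of these members 3 fell and 0 rose, and adjusted over the list alone 3 fell and 4 rose. Cyp3a11 fell (-5.07, 95% interval -6.91 to -3.19), as did Cyp2c29 (-3.26, -4.62 to -1.87) and Cyp3a13 (-2.22, adjusted p = 0.00736). The list did not pass (camera adjusted p = 0.319), with a median of 0.16 and a mean that was negative. By camera it passed after centring on standardised values (0.0442), with 8 of its 15 members higher. It also passed after median centring (0.0096), with 5 of 15 members higher. Camera compares a list with all genes, whose median then stood at -1.29, so that pass does not show a fall of the list. In the NRF2 and glutathione list 2 of 16 members rose and 0 fell, and adjusted over the list alone 3 rose and 4 fell. The 2 were Gsta2, a glutathione transferase (2.04, adjusted p = 0.0128), and Sod2, a mitochondrial superoxide dismutase (1.70, adjusted p = 0.0372). That list did not pass (camera adjusted p = 0.892).

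Further large rises in the deposited score were Moxd1, a monooxygenase-like gene (from 6.25 ± 0.149 to 6.84 ± 0.203, mean ± SD, n = 10 per diet; standardised difference 3.31, 1.91 to 4.68), Nnmt, which methylates nicotinamide (1.63), Saa1, an acute-phase protein (1.70), and Selenbp1 (3.84). Moxd1 was the only gene past the threshold with a deposited difference of at least 0.585, which would be 1.5-fold if scores were log2 values. Fits that left out 1 array gave 0 to 1 such genes, and array weights gave 0. Further large falls were Inmt (-1.79), Tmem86a (-3.20), Rflna (-5.62), Spc25 (-1.91), Ces1f (-1.70), Mme (-2.17) and Prxl2b (-3.40). The probe set used for Rflna carries a cross-hybridising suffix, and the other probe set of Rflna stood at 1.18 (adjusted p = 0.347). Nnmt, Ces1f and Saa1 had adjusted p-values of 0.046, 0.037 and 0.0366, and these calls were lost in 15, 12 and 8 of the 20 fits that left out 1 array (up to 0.0796, 0.0652 and 0.0630, without high-fat replicates 10, 10 and 8).

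Other lists gave at most a few members. Otc of the urea cycle (1.95) and Rpl10a of the ribosome (2.01) rose, and Uroc1 of amino acid breakdown (-2.01) and Rdh9 of retinol handling (-1.61, adjusted p = 0.0483) fell, without their lists passing. After median centring the signs of Otc (-0.0467) and Rpl10a (-0.945) turned. The call of Rdh9 was lost in 16 of the 20 fits that left out 1 array (up to 0.0820, without high-fat replicate 4). Of 32 oxidative phosphorylation genes, Ndufb3 rose (2.19, but -1.34 after quantile normalisation) and Ndufa6 (-2.18) and Sdhd (-1.76) fell, and 23 were below the low-fat mean (camera adjusted p = 0.0705). That list passed with array weights (0.0288), with the mean of a gene's probe sets (0.0233), without cross-hybridising probe sets (0.0377), after centring on standardised values (0.0382), and without low-fat replicate 1, 2, 7 or 9 or high-fat replicate 7, 8 or 9 (0.0144 to 0.0493). Of 22 acute phase genes, Itih3 (1.85, but -0.813 after median centring) and Saa1 rose and Apcs fell (-1.78). That list did not pass (camera adjusted p = 0.692) except after quantile normalisation (0.0206) and median centring (1.03e-07). In the circadian clock list 0 of 17 members passed. None of the 12 cell type lists passed by camera, from stellate cells (adjusted p = 0.0847) to Kupffer cells (adjusted p = 0.978). The stellate list, with 0 of 12 members past, did pass with the mean of a gene's probe sets (0.0177), after median centring (6.28e-06), and without low-fat replicate 4 (0.0345), high-fat replicate 8 (0.0476) or high-fat replicate 9 (0.0199). The collagen list (camera adjusted p = 0.0847, 0 of 18 members past) passed with the mean of a gene's probe sets (0.0233), after median centring, and without low-fat replicate 1 or 4 or high-fat replicate 8, 9 or 10 (0.00994 to 0.0392). Median centring lowers most genes and gave 21 of 42 lists past the threshold, so a pass there says little about a single list. Of 64 control probe sets 0 passed an adjusted p of 0.05 by limma (smallest 0.246) and 10 had an unadjusted p under 0.05, all lower on the high-fat diet. All 10 were among the 24 poly-A spike-in control probe sets. Single markers passed: Krt23 of bile duct cells (2.09) and Cela1 of pancreatic acinar cells (1.80) rose, and Mylpf of muscle fell (-1.99). Mylpf lay at 6.55, below the array median of 6.57, and its deposited score differed by -8.01e-06.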

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

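A gap test on single mice was run in 102 groups of 10, over the named genes and the scores of the lists past the threshold, and 5 groups had a mouse far from the others, while chance gives about 1 in 20. For Cyp51, high-fat replicate 9 lay below the rest (gap over range 0.513), and without it the adjusted p was 5.68e-05. For the fatty acid synthesis and desaturation score, high-fat replicate 9 was also low (0.563), and without it the camera adjusted p was 5.31e-05. For Etfb, high-fat replicate 7 was high (0.469), and without it the adjusted p was 0.0702, past the threshold no longer. For the lipoprotein and HDL score, high-fat replicate 7 was high (0.473), and without it the adjusted p was 0.0471. For Mylpf, low-fat replicate 4 was low (0.528), and without it the adjusted p was 0.00887.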

How the results depend on the processing

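The unmoderated model, array centring on standardised values, the B2 repeat and poly-A spike-in covariates, the permutation of mice and the removal of constant genes after quantile normalisation were chosen after seeing the data. The log2(value + pseudocount) setting does not apply to these scores and was not run. Quantile normalisation left 868 genes and 2676 probe sets with 1 value on all arrays, among them Itih3, Otc, Rpl10a, Cyp3a11, Calr, Hspd1 and Etfb, which give no value there; the others gave 1488 genes and 4164 probe sets (1572 and 4327 with the constant ones kept), and centring arrays on their medians 15098 genes, 38616 probe sets and 21 lists. Array medians were higher on the high-fat diet by 7.33e-05, which median centring takes from every gene; for quantile normalisation the cause was not tested. Of the other 37 named genes the sign turned for Ndufb3 (-1.34, adjusted p = 0.0598). After median centring the sign turned for Itih3 (-0.813), Otc (-0.0467), Rpl10a (-0.945), Hspd1 (-0.949), Etfb (-1.12) and Psma4 (-0.766). Of these only Etfb passed there (limma adjusted p = 0.0274). Camera compares a list with all genes, so its sign for the lipid droplet list turned too (adjusted p = 0.286), although 15 of 16 members kept theirs. Median centring also ended the calls of the fatty acid synthesis (0.613) and lipoprotein lists (0.145), and quantile normalisation those of the proteasome and lipoprotein (both 0.186) and lipid droplet lists (0.954). Without cross-hybridising probe sets Rflna stood at 1.18. A threshold of 0.01 left 212 genes and 272 probe sets, array centring on standardised values gave 1344 and 2504, and the B2 covariate 1020 and 1596; the last 2 settings included all 635 genes. The spike-in covariate gave 413 genes (374 of them shared) and 570 probe sets. The mean of a gene's probe sets gave 12 lists and an estimated correlation 3; the cause was not tested. The single gene past the deposited difference of 0.585, Moxd1, was lost with array weights (0) and is below the median level, so also with the upper features (0). Leaving out each array gave 498 to 720 genes, 768 to 1124 probe sets, 0 to 1 genes past that difference (0 without low-fat replicate 1, 2, 6, 9 or 10 or high-fat replicate 1, 2, 3, 5 or 6) and 5 to 11 lists (11 without high-fat replicate 9). Among named genes, 814 of 880 such values stayed past the threshold with the same sign, and the others were of Rdh9, Nnmt, Etfb, Ces1f, Saa1 and Inmt. Of 44 such genes the threshold of 0.01 ended 19 calls, the replicate block 11, the spike-in covariate 7 and the rank sum test 5. The lipoprotein list was lost in 9 of the 20 fits without 1 array and the lipid droplet list in 8. Replicate numbers do not pair the mice (same-number correlations from -0.159 to 0.260, and 1 of 10 low-fat mice correlated best with its own number); the replicate block gave 421 genes, 538 probe sets, 1 gene past the difference and 6 lists.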

Other observations

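Several genes outside the naming rule separated the diets completely and are given here after their values were seen. Aadat, an aminotransferase of lysine and kynurenine breakdown, was higher in all high-fat mice (6.32, 95% interval 4.08 to 8.53), as was the ribonuclease gene Ang (4.22, 2.58 to 5.83). The lipid transporter gene Abca3 (-3.70, -5.17 to -2.20) and Mgll, which cleaves monoacylglycerols (-3.14, -4.46 to -1.77), were lower in all high-fat mice. Ttr, an abundant plasma carrier protein, was also lower in all high-fat mice (-3.12), yet limma gave its representative probe set an adjusted p of 0.224, because its SD was so small that the shared prior raised it. The unmoderated model, added after seeing the data, gave 0.000942. Of the 4 probe sets of Ttr, 2 others were lower and passed limma over all probe sets (-2.46, adjusted p = 0.00562, and -1.96, adjusted p = 0.0258).

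Chaperone and cholesterol synthesis scores did not rise together among mice of the same diet. Within the low-fat diet Pearson's r was -0.70 (permutation p = 0.0231, adjusted over 4 relations 0.0926) and Spearman's rho -0.65 (p = 0.0492, adjusted 0.197), and r was -0.74 without the 2 mice farthest from the median. Within the high-fat diet r was -0.35 (p = 0.326) and rho -0.20 (p = 0.585), and r was -0.05 without 2 mice. Neither relation passed after adjustment.

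Among 100 splits of the 20 arrays, the real split included, 1 gave as many genes as the diets (635, highest other 8) and 1 as many probe sets (1043, highest other 6), so chance can be excluded for these counts. For genes with a deposited difference of at least 0.585, 1 split gave as many (1, highest other 0), which decides nothing, since the other splits called at most 8 genes at any difference. For gene lists by camera chance stays open: 34 of 100 splits gave at least the real 7 lists, with up to 14 in another split. Calls of single lists therefore lean on the permutation of mice, which passed 7 of 42 lists, 5 of them also past in camera. Its scores were scaled by the SD within the real diets, which can favour the real split, so its p-values may be too small.

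In the following tests, those of the nutritional axis, of clock time, of the spike-in controls and of a shared response were chosen after the values they bear on had been seen. The rise of endoplasmic reticulum chaperones was 2.47 SD (95% interval 1.74 to 3.20). It was 2.84 (2.17 to 3.52) with a clock gene score as a covariate and 2.51 (1.67 to 3.34) with the spike-in score, so neither score accounts for all of it. These scores measure clock time and labelling only roughly, so neither cause is excluded. With the B2 repeat control, which follows the largest axis of array differences within diets (correlation 0.857), the rise was 2.47 (1.71 to 3.22). That control differed by only -0.07 between diets (-1.03 to 0.90, permutation p = 0.891). As a covariate it could hardly change the rise, so it decides nothing. A nutritional axis stays open. The slope of amino acid breakdown on chaperone scores within diets (-0.40, p = 0.0178) predicts a difference of -0.99 between diets, and 0.146 was observed (joint standard error 0.480). That gap is beyond the bound set for the test and would have counted against the axis. Only after these values were seen was the test called undecided, because the relation passed in neither diet (r = -0.45, adjusted p = 0.257, and r = -0.60, adjusted p = 0.131, or -0.21 without 2 mice). A response of the liver to the diet also stays a candidate explanation, as a hypothesis.

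The rise of cholesterol synthesis was 1.30 SD (0.62 to 1.98). It was 1.05 (0.36 to 1.75) with the clock score as a covariate, 1.17 (0.41 to 1.93) with the spike-in score and 2.20 (0.95 to 3.45) with the chaperone score, so none of these scores alone accounts for all of it. The clock and spike-in scores measure clock time and labelling only roughly, so neither of those causes is excluded. With the B2 control the rise was 1.30 (0.60 to 2.00), which decides nothing, since that control hardly differed between diets (-0.07). The clock score, chosen after the data were seen, is the mean of 5 genes (Arntl, Npas2, Clock, Nfil3, Cry1) minus that of 10 (Nr1d1, Nr1d2, Per1, Per2, Per3, Dbp, Tef, Ciart, Bhlhe41, Hlf), unlike the mean of the circadian list (difference -0.16, permutation p = 0.300), and differed by -1.13 between diets (-2.41 to 0.15, permutation p = 0.0847). The spike-in score differed by -0.79 (-1.64 to 0.05, permutation p = 0.0694), so a part played by clock time or by labelling stays open. A response to the diet may account for the rise, as a hypothesis.

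The fall of Cyp3a genes covered 4 of 5 measured. Among them Cyp3a44 (-2.66, adjusted p = 0.00216) had a low-fat mean of 5.91, below the array median of 6.57. Cross-hybridisation to the abundant Cyp3a11 transcript predicts that the probe sets of the other Cyp3a genes follow Cyp3a11 among mice of the same diet. The bound written beforehand was a median correlation below 0.5 over the other 4 genes, and the value was 0.287 (bootstrap 95% interval -0.007 to 0.469), below that bound. As seen only afterwards, the bound was wrong to include Cyp3a16, which did not fall (0.18, adjusted p = 0.892; correlation -0.37). Over the 3 that fell the median was 0.479 (0.034 to 0.686), with Cyp3a44 at 0.094. Over the 2 of them above the array median it was 0.506 (0.132 to 0.736). Cross-hybridisation thus cannot be told apart from a fall of each gene with these few genes.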
